A study of Mus musculus with 2 samples.

How the data were processed

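Total RNA from adrenal glands was reduced of ribosomal RNA and made into strand-specific libraries with added ERCC spike-in RNA, from 300 ng of RNA, per the labels. Expected counts, TPM and FPKM per gene were deposited by the authors for each library, made from transcriptome alignments to mm10 with GENCODE M21, per the library notes in the series. The deposited transcript tables of the same pipeline gave expected counts, TPM and each transcript's percent of its gene, per the file headers. A further deposited transcript table gave estimated counts and TPM made directly from the reads, and is called the second quantifier. The deposited gene tables also held the bounds of a TPM interval, a signal in TPM units per the file headers, which were not used here, and the posterior SD of each count, used in the closing section only. Aligner and quantifier names and versions are not given in the sources used here, and the column names are those that RSEM and kallisto write. TPM was scaled by the authors over all 81881 features of the gene table, so abundant short RNA lowers the TPM of every other gene.

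All 55536 annotated genes of GENCODE M21 were matched by identifier. Spike-ins, phiX174 and 26248 entries with numeric identifiers, which name no gene, stayed out of library sizes, and spike-ins held 0.468% and 0.504% of the counts of replicates 1 and 2. Transcript values of the second quantifier were summed per gene. Expected counts were rounded to whole numbers before ratios and dispersion were computed. Ratios used TMM-scaled totals from edgeR 4.0.16 and a prior count of 0.5 in R 4.3.3, and the dispersion came from edgeR with filterByExpr and 1 group. Size factors of DESeq2 1.42.0 were an alternative. The TMM factors were 0.999 and 1.00. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Because ratios use counts and TPM divides by a length weighted over transcripts, the ratios and the TPM values of a gene with shifting transcripts can differ.

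A gene was called detected at 1 TPM or more in both libraries. The ratios of a list used members with a mean count of at least 20, and each median was placed among 10000 random lists of the same size matched on mean count in 20 bins. Quantifiers were compared with a pseudocount of 0.1 TPM. Standard errors of ratios come from Poisson counting, and reads are not independent molecules, so they cover counting error only. No p-values were computed across genes. The gene lists, 33 in number with 387 different genes of which 386 matched a symbol, the comparisons and the alternatives were fixed before the data were examined, except where an alternative is said to have been added later. The tests of explanations in the closing section were chosen later, as said there. Entries that share a symbol were summed.

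Genes named in the text followed a rule set in advance. It takes every detected member of the steroid and catecholamine lists, the 4 highest members of each other list and members stated as not detected, and the 20 highest genes outside mitochondrial, spike-in, ribosomal and small structural RNA. It takes the 12 highest and 12 lowest ratios among genes with a mean count of at least 100 and at least 10 in the lower library, and the 3 members farthest from 0 of each list in the outer 2.5% of its random lists on either side. It also takes the 10 largest differences each way between quantifiers among genes with a mean of 5 TPM or more in either. A few genes that the rule takes are not reported here.

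The procedure was tested on simulated counts with the real means and library sizes. Among genes changed by 1.5 on the log2 scale 95% were recovered at 2-fold in the right direction, and 100% of those changed by 2.5, over 100 genes each, while 0.145% of 12376 unchanged genes passed. Every simulated gene had the same coefficient of variation of 14.1%, returned as 14.2% when no gene was changed. In the data the common value was 8.85%, with a trend from 16.6% at the lowest to 7.78% at the highest expression. The simulated 0.145% is therefore not the share to be awaited in these 2 libraries. Alternatives tried were other scalings, count and TPM limits, FPKM, the second quantifier, other pseudocounts, leaving out each library, and shares of TPM.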

Results

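Total RNA was measured in the adrenal gland of adult male mice of a cross labelled 5xFAD by CAST, aged 8 to 10 months. 5xFAD is a transgenic mouse model of amyloid deposition, and CAST is a wild-derived inbred strain. Reads of CAST alleles were counted against the mm10 reference like all others, and the effect of this on the values was not analysed here. The series held 2 libraries of this 1 group, labelled biological replicates 1 and 2, and no other genotype, tissue or treatment was analysed here. The labels give a separate biosample for each library and the same donor entry for both, so it is not known whether the spread between them is that between animals. Counts of the annotated genes summed to 29204658 in replicate 1 and 26322473 in replicate 2. With 1 group there was nothing to test between groups, and a sign-flip over 2 libraries cannot give a two-sided p below 0.5, so none was run. TPM values below are means ± SD over the 2 libraries (n = 2), and errors of ratios between the libraries cover counting error only.

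The first question was which genes of hormone synthesis the gland expressed and at what level. Genes of steroid synthesis stood among the most abundant mRNAs. Star, which carries cholesterol into mitochondria, was at 5704 ± 171 TPM, Hsd3b1 at 4646 ± 70.1 TPM, and Cyp11a1, the side-chain cleavage enzyme, at 2808 ± 86.2 TPM. The 21-hydroxylase gene Cyp21a1 was at 2617 ± 549 TPM and Cyp11b1, which completes corticosterone synthesis, at 1694 ± 38.1 TPM. All 20 members of the steroidogenesis list were detected, meaning at least 1 TPM in both libraries, and their median was 341 ± 7.53 TPM. The 11 catecholamine genes were all detected too, with a median of 37.2 ± 1.92 TPM, so that the steroidogenesis median was 9.18 ± 0.677 times as high (SD, n = 2), a gap larger than the spread between the libraries.

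Below the leading steroidogenic genes, Akr1b7 was at 797 ± 155 TPM, the lipoprotein receptor gene Scarb1 at 789 ± 52.2 TPM, and the electron-transfer genes Fdxr and Fdx1 at 734 ± 3.31 and 684 ± 126 TPM. Soat1, which esterifies cholesterol, was at 453 ± 6.34 TPM. Cyp11b2, the aldosterone synthase gene, was at 229 ± 8.73 TPM, and the steroidogenic transcription factor gene Nr5a1 at 136 ± 14.6 TPM. Hsd3b6 was at 94.99 ± 22.8 TPM, the corticotropin receptor gene Mc2r at 87.1 ± 3.22 TPM, Por at 73.6 ± 0.877 TPM and the receptor accessory gene Mrap at 69.8 ± 6.29 TPM. Lipe was at 47.4 ± 4.86 TPM and Stard4 at 10.5 ± 2.62 TPM. The lowest members were Cyp17a1, the 17-hydroxylase gene, at 1.36 ± 0.113 TPM and Nr0b1 at 1.35 ± 0.255 TPM. Cyp11a1 was 2075 ± 236 times as high as Cyp17a1.

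Among catecholamine genes, Th, the rate-limiting enzyme, was at 213 ± 4.57 TPM, Dbh at 186 ± 17.4 TPM and Pnmt, which makes adrenaline from noradrenaline, at 183 ± 51.5 TPM. The ratio of Pnmt to Dbh was 0.843 in replicate 1 and 1.11 in replicate 2, so the order of these genes differed between the libraries. Cyb561 was at 101 ± 9.63 TPM, Ddc at 37.2 ± 1.92 TPM and Maoa at 31.0 ± 0.636 TPM. Gch1 was at 19.4 ± 2.61 TPM. The vesicular transporter gene Slc18a1 was at 16.6 ± 2.60 TPM and its paralog Slc18a2 at 9.07 ± 0.311 TPM, and the noradrenaline transporter gene Slc6a2 was at 5.03 ± 0.346 TPM. Star was 26.8 ± 0.229 times as high as Th.

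**Figure D1:**
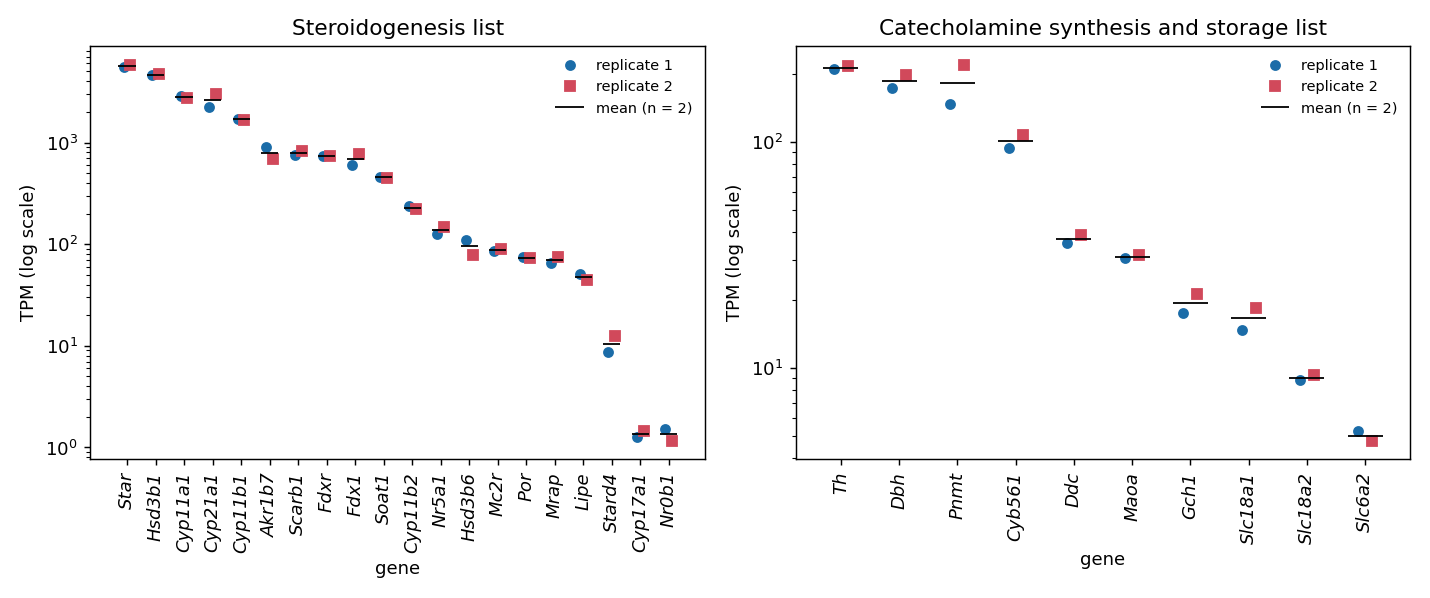
TPM on a log axis of the members of the steroidogenesis list (left) and the catecholamine list (right) that the text names, with a circle for replicate 1, a square for replicate 2 and a bar at their mean. Star leads the left panel at 5704 TPM and Th the right panel at 213 TPM.

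Genes of the outer cortical zones were all present, while markers of the transient X-zone were near the detection floor. All 12 zona glomerulosa genes were detected, with a median of 78.3 ± 14.1 TPM. The potassium channel gene Kcnk3 led them at 489 ± 22.1 TPM, followed by Cyp11b2, Dab2 at 170 ± 4.11 TPM and the angiotensin receptor gene Agtr1a at 129 ± 0.530 TPM. The 6 zona fasciculata genes had a median of 1000.3 ± 44.1 TPM and included Hsd3b1, Cyp11b1, Akr1b7 and Abcb1b, the last at 1204 ± 243 TPM. Cyp11b1 was 7.40 ± 0.116 times as high as Cyp11b2 in TPM, and 4.09 ± 0.179 times in the second quantifier. These neighbouring genes are close paralogs, so their split is uncertain. The X-zone gene Akr1c18 had 2 counts in replicate 1 and 0 in replicate 2, where 3 counts would be 0.104 and 0.112 TPM. Pik3c2g had 0 and 1 counts, and Thrsp, which adipocytes also express, was at 22.2 ± 0.672 TPM.

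The chromaffin cell list had all 18 members detected, led by the granin genes Chga at 861 ± 77.2 TPM, Chgb at 692 ± 66.9 TPM and Scg2 at 422 ± 39.6 TPM, and by Npy at 241 ± 13.8 TPM. In the cholesterol list 20 of 21 members were detected, led by Dhcr7 at 263 ± 49.9 TPM, Msmo1 at 102 ± 13.6 TPM, Hmgcs1 at 84.5 ± 5.73 TPM and Fdps at 77.1 ± 11.8 TPM.

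Markers of supporting cell types were measured in the same bulk tissue. All 12 endothelial genes were detected, led by Plvap at 82.6 ± 0.113 TPM, Egfl7 at 81.0 ± 2.31 TPM, Emcn at 48.2 ± 3.41 TPM and Eng at 44.3 ± 0.969 TPM. In the capsule and fibroblast list 11 of 12 were detected, led by Dcn at 74.9 ± 9.63 TPM, Nr2f2 at 49.5 ± 5.32 TPM, Col1a2 at 21.1 ± 1.04 TPM and Col3a1 at 13.3 ± 2.74 TPM. The smooth muscle list had 7 of 8, with Tagln at 32.2 ± 7.73 TPM, Rgs5 at 10.8 ± 0.849 TPM, Acta2 at 7.35 ± 1.68 TPM and Des at 4.15 ± 0.226 TPM. The 15 macrophage genes were all detected, with Cd74 at 172 ± 41.7 TPM, Lyz2 at 114 ± 45.7 TPM, H2-Aa at 57.2 ± 12.7 TPM and C1qb at 31.8 ± 2.24 TPM. In the lymphocyte list 2 of 12 were detected, Ighm at 28.8 ± 3.95 TPM and Ptprc at 5.17 ± 0.283 TPM, while Cd3e and Nkg7 were at 0.620 ± 0.0566 and 0.555 ± 0.177 TPM. In the Schwann list 5 of 9 were detected, including Pmp22 at 31.8 ± 2.72 TPM, Mbp at 5.38 ± 0.113 TPM and S100b at 2.88 ± 0.962 TPM.

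Genes of fat and of neighbouring tissues were detected to unequal extents. All 9 white adipocyte genes were detected, with a median of 60.2 TPM in replicate 1 and 36.1 TPM in replicate 2. Car3 was at 188 ± 60.2 TPM, Fabp4 at 176 ± 68.0 TPM, Plin1 at 76.5 ± 19.1 TPM and Adipoq at 50.6 ± 20.4 TPM. Of the brown adipocyte list 4 of 8 were detected, Cox8b at 24.7 ± 1.37 TPM, Cox7a1 at 19.4 ± 2.55 TPM, Cidea at 3.34 ± 1.02 TPM and Ucp1 at 2.87 ± 1.47 TPM. In the kidney list 1 of 11 genes was detected, Aqp2 at 1.35 ± 0.481 TPM, with Miox, Cubn and Lrp2 at 0.390 ± 0.113, 0.0900 ± 0.0424 and 0.0250 ± 0.0354 TPM. In the liver and pancreas list 1 of 10 genes was detected, Cela1 at 34.1 ± 1.08 TPM. Alb, Ttr and Apoa1 were at 0.530 ± 0.269, 0.190 ± 0.0424 and 0.0600 ± 0.0283 TPM. The pancreas genes Prss2, Cpa1, Pnlip and Amy2a5 had 0 counts in the gene table in both libraries. None of the 7 skeletal muscle genes reached the limit in both libraries, with Mylpf, Acta1, Tnnt3 and Ckm at 0.705 ± 0.276, 0.450 ± 0.0141, 0.285 ± 0.205 and 0.135 ± 0.148 TPM. In the erythroid list 5 of 7 matched genes were detected, with Hba-a1 at 286 ± 35.7 TPM, Hbb-bs at 266 ± 37.1 TPM, Hba-a2 at 182 ± 14.9 TPM and Hbb-bt at 28.5 ± 2.84 TPM. The globin genes are near-identical copies and their split is uncertain.

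Stress, clock and steroid-responsive genes were detected at moderate levels. Jun was at 162 ± 15.1 TPM, Nr4a1 at 61.7 ± 4.11 TPM, Junb at 16.2 ± 3.25 TPM and Nr4a3 at 15.9 ± 1.05 TPM, within an immediate early list of which 11 of 13 were detected. The heat shock list, with 10 of 10, was led by Hspa8 at 410.4 ± 6.60 TPM, Hspd1 at 196 ± 26.5 TPM, Hspe1 at 108 ± 16.0 TPM and Hsp90aa1 at 98.3 ± 13.9 TPM. Of the 15 clock genes 14 were detected, led by Dbp at 128 ± 0.523 TPM, Nr1d1 at 70.9 ± 1.28 TPM, Tef at 67.3 ± 8.14 TPM and Nr1d2 at 47.8 ± 1.12 TPM. The glucocorticoid response list, with 10 of 11, was led by the metallothionein genes Mt1 at 126 ± 25.9 TPM and Mt2 at 87.8 ± 12.3 TPM, then Sgk1 at 57.2 ± 5.76 TPM and Fkbp5 at 56.1 ± 10.5 TPM. In the interferon list 11 of 13 were detected, among them Bst2 at 19.7 ± 1.68 TPM, Xaf1 at 9.70 ± 2.32 TPM and Rsad2 at 6.12 ± 1.02 TPM. Of the 15 proliferation genes 7 were detected, among them Pcna at 18.9 ± 0.191 TPM, Mcm2 at 15.3 ± 2.05 TPM, Mcm6 at 5.32 ± 0.191 TPM and Tyms at 4.27 ± 0.127 TPM, while Mki67, Top2a and Cdk1 were not.

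Genes tied to the amyloid model and to sex were measured against the mouse reference alone, so transcripts of human transgenes were not quantified separately. All 16 amyloid pathway genes were detected, led by Apoe at 378 ± 61.5 TPM, Aplp2 at 212 ± 9.17 TPM, App at 119 ± 0.926 TPM and Mapt at 59.9 ± 8.92 TPM. The Y-linked genes Eif2s3y at 35.2 ± 3.18 TPM, Ddx3y at 32.1 ± 0.163 TPM, Uty at 16.2 ± 0.219 TPM and Kdm5d at 9.78 ± 0.559 TPM were detected, and Xist was at 0.0550 ± 0.0212 TPM. The hormone receptor list, with 11 of 13, was led by Insr at 48.5 ± 4.91 TPM, Igf1r at 32.8 ± 1.44 TPM, Prlr at 29.7 ± 1.49 TPM and Ghr at 21.7 ± 4.35 TPM. The 14 antioxidant genes were all detected, led by Sod1 at 394 ± 2.28 TPM, Gpx4 at 224 ± 2.56 TPM, Prdx3 at 224 ± 10.2 TPM and Prdx1 at 169 ± 3.10 TPM.

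The next question was how the sequenced RNA divided among classes. Protein-coding genes held 73.1% of gene counts in replicate 1 and 73.7% in replicate 2, with long intergenic noncoding RNA at 8.25% and 8.00%. Small structural RNA of the class that holds Rn7s1, Rn7s2 and Rn7sk took 8.76% and 8.79% of counts but 44.1% and 44.8% of TPM, since TPM divides by length. Mitochondrial ribosomal RNA held 7.03% and 6.63% of counts. Mitochondrial-encoded mRNA, which is part of the protein-coding share, held 2.64% and 2.82%. Its leading members were mt-Co1 at 6475 ± 297 TPM, mt-Cytb at 3440 ± 252 TPM, mt-Co3 at 3167 ± 252 TPM and mt-Atp6 at 2998 ± 497 TPM. In the second quantifier mt-Atp6 was at 6348 ± 578 TPM, above mt-Co1 at 6206 ± 283 TPM, so their order is uncertain. In all, 14173 genes were detected, of which 12371 were protein-coding, and the 10 most abundant genes held 25.6% and 25.2% of counts.

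Among the 20 most abundant genes outside mitochondrial and small structural RNA, Malat1 (chromosome 19, 5795690 to 5802672, mm10) came first in the gene table at 12660 ± 133 TPM. In the second quantifier Malat1 was at 6412 ± 247 TPM, below the noncoding entry Gm26917 at 9791 ± 175 TPM. Star (chromosome 8, 25806555 to 25815982) was the leading protein-coding gene, followed by Hsd3b1. Cyp11a1 and Cyp21a1 came next, and their order differed between the libraries. Eef1a1 was at 2032 ± 6.06 TPM, Srd5a2, a steroid 5-alpha-reductase gene, at 1294 ± 11.7 TPM, Meg3 at 1122 ± 13.4 TPM, Actb at 995 ± 22.9 TPM, Fth1 at 983 ± 41.0 TPM and Rpl41 at 872 ± 14.5 TPM. Gm26917 at 11443 ± 29.3 TPM and Gm42418 at 3119 ± 147 TPM are neighbouring entries on chromosome 17, annotated as long intergenic noncoding RNA. Their 867002 and 159809 counts in replicate 1 are part of that class's share. Classes followed the annotation, and whether these entries hold reads of ribosomal RNA was not analysed here. The pseudogenes Gm28661, Gm10925, Gm28437 and Gm29216, at 5378 ± 731, 4973 ± 191, 2085 ± 716 and 1815 ± 160 TPM, lie within one stretch of chromosome 1. They resemble mitochondrial genes, so their values and those of the mitochondrial genes are uncertain. The ribosomal protein list, with all 22 members detected, included Rplp1 at 678 ± 6.65 TPM, Rps24 at 580.0 ± 2.81 TPM and Rps4x at 352 ± 3.46 TPM. The abundant noncoding list was led by Rn7sk at 52990 ± 3339 TPM, followed by Malat1, Rpph1 at 6999 ± 209 TPM and Rmrp, summed over 2 overlapping entries, at 6837 ± 502 TPM. In the second quantifier Rpph1, at 12002 ± 290 TPM, and Rmrp, at 8974 ± 1286 TPM, were above Malat1. The imprinted list, with 13 of 14, was led by Meg3, Rian at 464 ± 0.714 TPM, Dlk1 at 308 ± 50.03 TPM and Cdkn1c at 89.4 ± 8.87 TPM.

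The libraries were then compared with each other to see how far 2 libraries of the same label differed. Most adipocyte and immediate early genes were lower in replicate 2, while most cholesterol, catecholamine, clock and interferon genes were higher there. The common biological coefficient of variation was 8.85% over 17359 genes, with a trend from 16.6% at the lowest to 7.78% at the highest expression. Across 26811 genes Pearson's r of log2(TPM + 1) was 0.990 and Spearman's rho of TPM was 0.952, and genes are not independent replicates. A chi-square over 18032 genes was 9.61 per degree of freedom, where independent sampling of reads gives about 1, and reads are not independent.

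**Figure D2:**
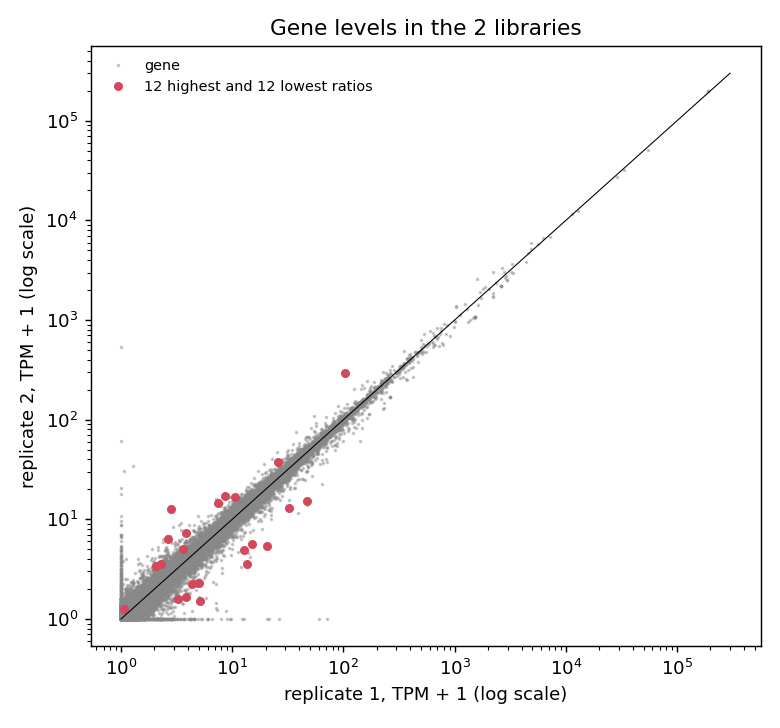
TPM + 1 of each gene in replicate 1 (x, log axis) and replicate 2 (y, log axis), with the 12 highest and 12 lowest ratios marked. The marked genes were taken among those with a mean count of at least 100 and at least 10 in the lower library. Pearson's r of log2(TPM + 1) was 0.990 across 26811 genes.

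White adipocyte genes were the list farthest below 0, with a median log2 ratio of replicate 2 to replicate 1 of -0.69 and all 9 members lower in replicate 2. Lep, the leptin gene, was at -1.47 ± 0.06 (SE), Fabp4 at -0.87 ± 0.03 and Cidec at -0.86 ± 0.05. The brown adipocyte median was -0.64 over 5 members, 4 of them lower in replicate 2, with Ppargc1a at -1.52 ± 0.35, Ucp1 at -1.10 ± 0.20 and Cidea at -0.64 ± 0.22. The most abundant members, Cox8b and Cox7a1, were at 0.10 ± 0.15 and -0.28 ± 0.17. Kidney genes had too few counts for the main comparison, and with a mean count of at least 5 their median over 4 members was -1.14, below its random range of -0.76 to 0.66. Aqp2 was at -0.75 ± 0.30 and Cubn at -1.04 ± 0.43, and Lrp2 had 24 and 0 counts. Immediate early genes had a median of -0.22 with 10 of 13 lower, among them Atf3 at -1.55 ± 0.26, Dusp1 at -0.83 ± 0.08 and Zfp36 at -0.68 ± 0.09, although Nr4a1 was at 0.42 ± 0.04 in counts, with a TPM of 64.6 in replicate 1 and 58.8 in replicate 2. Macrophage genes had a median of -0.21, with Lyz2 at -0.86 ± 0.04, Cd68 at -0.71 ± 0.12 and Tyrobp at -0.57 ± 0.14, although Cd74 and H2-Aa were at 0.48 ± 0.03 and 0.45 ± 0.05. The glomerulosa median was -0.10, with Kcnk9 at -0.56 ± 0.01, Hsd3b6 at -0.53 ± 0.03 and Agtr1b at -0.37 ± 0.12.

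In the other direction, interferon genes had a median of 0.54 with 12 of 13 members higher in replicate 2, among them Oas2 at 1.07 ± 0.37, Oas1a at 1.04 ± 0.27 and Ifit3 at 0.74 ± 0.14. Cholesterol genes had a median of 0.26 with 17 of 20 higher, among them Dhcr7 at 0.40 ± 0.02. Erythroid genes had a median of 0.25, with Alas2 at 0.32 ± 0.16, Hbb-bs at 0.27 ± 0.03 and Hba-a1 at 0.25 ± 0.03. Clock genes had a median of 0.20, with Per2 at 0.78 ± 0.03, Ciart at 0.65 ± 0.16 and Cry1 at 0.61 ± 0.11. Chromaffin genes had a median of 0.18 with 17 of 18 higher, including Hand2 at 0.47 ± 0.06, Scg3 at 0.38 ± 0.08 and Syt1 at 0.35 ± 0.07. Catecholamine genes had a median of 0.16, with Pnmt at 0.57 ± 0.03, Slc18a1 at 0.28 ± 0.06 and Gch1 at 0.26 ± 0.05. Glucocorticoid response genes had a median of 0.14, with Tsc22d3 at 0.41 ± 0.05, Fkbp5 at 0.36 ± 0.03 and Mt1 at 0.36 ± 0.05.

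Imprinted genes had a median of 0.13, with H19 at 0.67 ± 0.44, Plagl1 at -0.35 ± 0.11 and Dlk1 at 0.32 ± 0.02, and in the second quantifier their median of 0.070 lay inside its random range of -0.065 to 0.074. Mitochondrial-encoded genes had a median of 0.12, with mt-Nd3 at 0.36 ± 0.02, mt-Atp6 at 0.33 ± 0.01 and mt-Nd4l at -0.25 ± 0.02. In the second quantifier mt-Atp6 was at 0.15. Hormone receptor genes had a median of 0.10 with Pgr at 1.09 ± 0.43, Ghr at -0.45 ± 0.06 and Adcyap1r1 at 0.39 ± 0.04. These 15 of the 28 lists with enough counts lay outside the central 95% of 10000 random lists matched on expression. Genes of a list vary together and random genes do not, so these percentiles describe the 2 libraries only. The other 13 lay inside it, with medians of -0.002 for steroidogenesis, 0.0008 for ribosomal proteins, -0.006 for heat shock, -0.002 for the sex-linked genes and 0.02 for the amyloid pathway. Within the same range were zona fasciculata at 0.04, antioxidant at 0.06, capsule and fibroblast at 0.07, endothelial at -0.03, abundant noncoding at -0.05, Schwann at -0.06, smooth muscle at -0.12 and proliferation at -0.12. A median near 0 can hold opposite shifts. Of the 20 steroidogenesis genes 10 were higher in replicate 2 and 10 lower, among them Cyp21a1 at 0.41 ± 0.01 and Akr1b7 at -0.41 ± 0.01. Scaled by spike-ins, every median fell by 0.10 together with its random lists. Hormone receptor genes were then at -0.000847, mitochondrial-encoded at 0.01, imprinted at 0.02, glucocorticoid response at 0.04, catecholamine at 0.06, chromaffin at 0.08, clock at 0.09, erythroid at 0.15, cholesterol at 0.16, glomerulosa at -0.20 and macrophage at -0.31. Steroidogenesis was at -0.11.

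**Figure D3:**
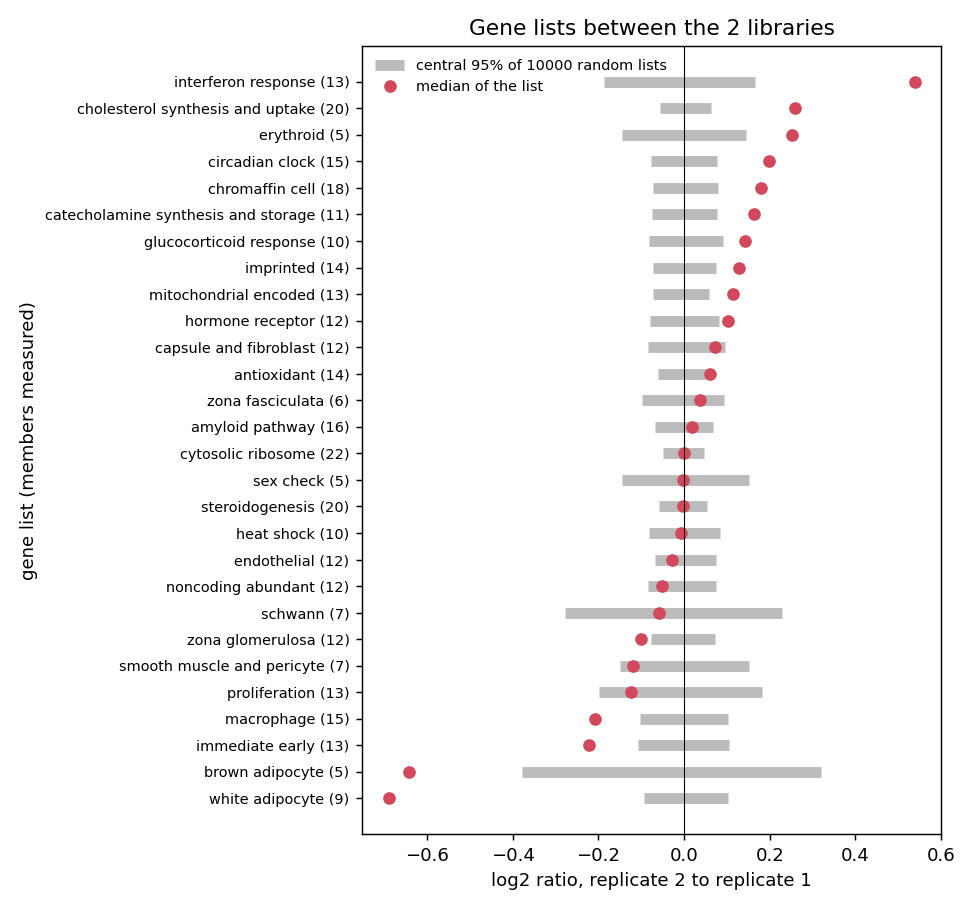
Median log2 ratio of replicate 2 to replicate 1 for each of 28 gene lists (points), with the central 95% of 10000 random lists matched on expression (grey bars) and the number of members measured in parentheses. White adipocyte genes lie lowest at -0.69 and interferon genes highest at 0.54.

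Single genes seldom differed by 2-fold. Of 12594 genes with a mean count of at least 100, 13 were at least 2-fold higher in counts in replicate 2 and 31 at least 2-fold lower, and 25 of these 44 were so in the second quantifier as well. Scaled by spike-ins 12 were higher and 47 lower, and the second quantifier alone gave 17 and 51. The split was 259 and 329 with a mean count of at least 10, and 4 and 5 with at least 500. The genes named next also had at least 10 counts in the lower library, as did 12588 of the 12594. Larger ratios of the remaining genes are not given here. Ttn, the titin gene of striated muscle, was 11.7-fold higher in replicate 2, with 24 and 258 counts but 0.0700 and 0.250 TPM. Masp1 was 3.30-fold, the alcohol dehydrogenase gene Adh1 2.80-fold and the chemokine receptor gene Ackr3 2.22-fold higher. Gm4070 and Gm14288 were 2.16-fold and 2.20-fold higher, and both quantifiers gave at least 2-fold for these 6 genes. Gm42742, an entry of Zc3h11a, Gm20388, Gm10273, Ugt1a6b and Nutf2 were 1.95-fold to 2.57-fold higher, and their calls are uncertain because the second quantifier did not give 2-fold, or a paralog or overlapping gene shares their reads.

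Among the lowest ratios within the same count limits, Egr3, an immediate early transcription factor gene, was 5.61-fold lower in replicate 2. Gpnmb was 4.23-fold lower, Perm1 4.01-fold and the fibronectin gene Fn1 3.57-fold. Msl3l2 was 3.01-fold lower, Lep 2.78-fold and the aquaglyceroporin gene Aqp7 2.66-fold. Pagr1a was 3.68-fold lower but overlaps Pagr1b and Gm42742, and Gm42633 and Gm43490, at 4.22-fold and 2.72-fold, overlap Scarb1 and Cacna2d1 on the same strand. A further entry of Zc3h11a was 5.00-fold lower while its overlapping entry was 2.24-fold higher, so neither describes the gene. Gm8430, a processed pseudogene, was 3.19-fold lower with no count in the second quantifier.

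The series also allowed the gene values to be set against those of the second quantifier. For protein-coding genes at 1 TPM or more the quantifiers gave closely related values, with Pearson's r across genes of 0.984 in replicate 1 and 0.982 in replicate 2, against 0.891 and 0.884 over genes of all classes, while most snoRNA, snRNA and miRNA genes were lower in the second. Of 15174 genes, 759 were at least 2-fold higher and 433 at least 2-fold lower in the second quantifier in both libraries, and at 5 TPM or more 179 were higher and 264 lower. Of 107 snoRNA genes 104 were lower, as were 41 of 44 snRNA genes and 25 of 25 miRNA genes, against 34 of 12613 protein-coding genes. Processed pseudogenes were the largest class of losses, with 175 of 610 lower and 118 higher. In the class that holds Rn7sk 11 of 47 genes were lower and 14 higher. The largest losses, all listed at 0 in the second quantifier, were the snRNA entries Gm24407, Gm24265 and Gm23238 at 1977 ± 358, 1960.2 ± 384 and 924 ± 95.2 TPM, the snoRNA genes Gm22988, Gm26447, Snord15b, Gm22486 and Snora74a, the miRNA gene Mir703 and Rpl10-ps3. The mitochondrial gene mt-Atp8 was at 2345 ± 23.6 TPM in the gene table and 16.7 ± 20.7 TPM in the second quantifier. Its overlapping neighbour mt-Atp6 went the other way, at 2998 ± 497 and 6348 ± 578 TPM. The chromosome 1 pseudogene Gm10925 was also lower in the second quantifier, at 4973 ± 191 and 145 ± 72.4 TPM. In replicate 1 Gm10925 held 80089 counts in the gene table and mt-Atp8 7034. Which entry's reads went to mt-Atp6 in the second quantifier was not tested.

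Of the 759 gains, 174 were long intergenic noncoding RNA genes, 156 protein-coding genes, 145 unconfirmed transcript entries (TEC) and 118 processed pseudogenes. Among the 10 largest, Gm19220, a processed pseudogene, was at 0.0300 ± 0.0424 TPM in the gene table and 2908 ± 119 TPM in the second quantifier, and Gm47283 at 0 and 119 ± 12.1 TPM. Rpl36a-ps3, Gm28438, Gm42857, Gm38356, Gm49274, Gm47673, Gm26905 and Gm48836 were likewise near 0 in the gene table and at 32.0 to 103 TPM in the second. The quantifiers disagreed on each of these, so their values are uncertain. Gm26905 overlaps Gm45635 and Gm48836 overlaps Syne1, and the part of gene copies was not tested.

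**Figure D4:**
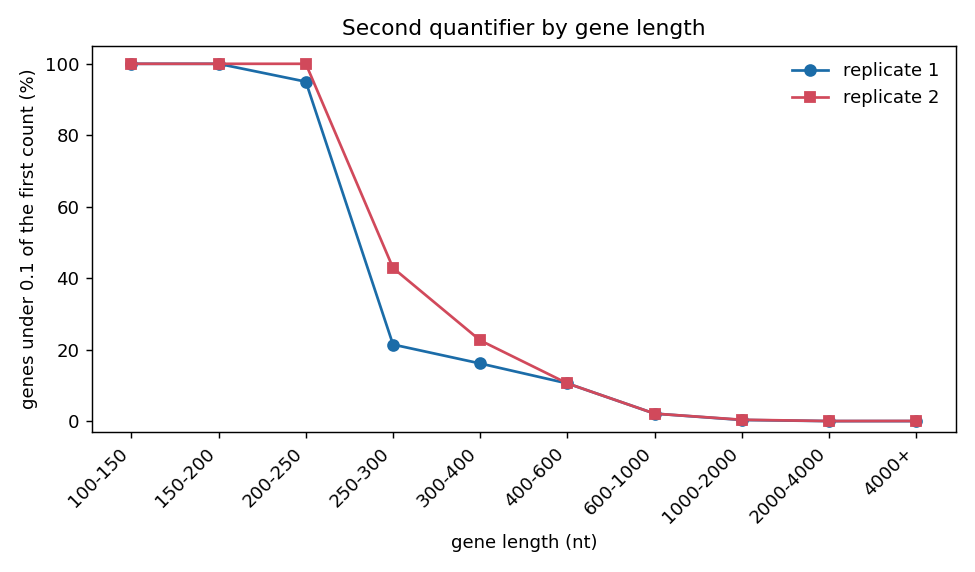
Percent of genes (y) whose count in the second quantifier was under 0.1 of the gene table's count, by gene length in nt (x), for replicate 1 (circles) and replicate 2 (squares), among genes with a mean count of at least 100. From 100 to 200 nt 100% of genes fell under that limit in both libraries, from 300 to 400 nt 16.1% and 22.6%, and from 1000 to 2000 nt 0.319% and 0.378%.

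Finally, transcript shares were compared for the steroid and catecholamine genes. Of 31 genes, 6 had a single annotated transcript, and for 24 of the other 25 both quantifiers gave the same leading transcript. The median share of the leading transcript was 81.1% over those 25 genes. Cyp11a1-201 held 96.6% ± 0.434 (SD, n = 2) of Cyp11a1, Cyp21a1-201 held 93.7% ± 0.173 of Cyp21a1 and Th-201 held 100% ± 0 of Th. In the second quantifier these shares were 90.1% ± 0.0192, 90.1% ± 1.58 and 87.3% ± 0.372. Star was split, with Star-202 at 54.3% ± 1.36, and so was Soat1, with Soat1-201 at 33.4% ± 1.59. For Ddc the gene table's quantifier led with Ddc-202 at 64.0% ± 5.25 and the second with Ddc-210 at 85.2%. Slc6a2-201 held 40.6% of Slc6a2 in replicate 1 and 87.4% in replicate 2, so its share was not stable between the libraries.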

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

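Reads outside the gene measurements were present in both libraries. The entry for phiX174, the genome of a phage used as a sequencing control, held 223 counts in replicate 1 and 204 in replicate 2, above the 3 counts that a count of 0 allows. These were 0.000760% and 0.000771% of all counts, with exact binomial 95% intervals of 0.000664% to 0.000867% and 0.000669% to 0.000884% that overlap and cover counting error only.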

How the results depend on the processing

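The count of detected genes, the share of protein-coding counts and the list levels stayed within the spread or within 1.5 times when either library was left out. With 2 libraries a mean cannot move by more than their SD, so leaving out a library says nothing about its stability. One scaling factor moves a list and its random lists alike, so the 15 lists outside their range could not change in number under other scalings. A mean count of at least 5 gave 16 with kidney genes added, and the second quantifier gave 15, of which 14 were the same, with kidney genes gained and imprinted genes lost at a median of 0.07 against 0.13. Scaling by spike-ins moved all ratios by 0.10 on the log2 scale and turned the hormone receptor median to -0.000847. The 44 genes at 2-fold became 59 when scaled by spike-ins, 588 with a mean count of at least 10, 9 with at least 500, 68 in the second quantifier and 25 when both quantifiers were required, the last chosen after seeing the data. In the second quantifier 87 of 150 TPM values and 21 of 33 list medians were classed as moved. The second quantifier moved the ratio of steroid to catecholamine medians from 9.18 to 12.7 and the median share of the leading transcript from 81.1% to 74.4%, and gave Gm8430, with no count there, a ratio of 0.188. Without a filter the coefficient of variation was 10.2%, and with a pseudocount of 0.1 the correlation was 0.972. At 5 TPM or more, 443 genes differed between quantifiers, against 1192. Shares of TPM were 36.9% for protein-coding genes and 3.18% for mitochondrial-encoded mRNA. Apart from settings whose construction sets the count, the cause was not tested. Alternatives also added after seeing the data gave 42 genes at 2-fold among genes of at least 300 nt, and 15 lists outside their range against random lists of protein-coding genes. Low counts limit Lrp2, H19, Pgr, Cubn, Oas2 and Ppargc1a, among others.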

Other observations

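The cytochrome P450 and nuclear receptor families were described after the data were seen. Of 94 protein-coding cytochrome P450 genes 24 were detected, and the 4 highest were the steroid enzymes Cyp11a1, Cyp21a1, Cyp11b1 and Cyp11b2. The next was Cyp4f13 at 40.2 ± 1.83 TPM (SD, n = 2), followed by Cyp2e1 at 25.6 ± 4.05 TPM and Cyp4b1 at 19.2 ± 0.148 TPM, and Cyp17a1 came last of the 24 at 1.36 ± 0.113 TPM. Of 47 nuclear receptor genes 37 were detected. Nr5a1 led at 136 ± 14.6 TPM, followed by the clock repressor gene Nr1d1 at 70.9 ± 1.28 TPM, Nr4a1 at 61.7 ± 4.11 TPM and Nr2f2 at 49.5 ± 5.32 TPM. The oxysterol receptor gene Nr1h2 was at 48.6 ± 1.40 TPM.

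For the patterns that follow, the prediction for the second adipocyte list was written before its result was seen, and the other tests were chosen only after their results had been seen in part. No biological explanation was tested, because the series holds a single group.

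White adipocyte genes were lower in replicate 2. A lower share of cortex in replicate 1 would raise the genes of all other cell types there alike, but the highest median among the endothelial, Schwann and chromaffin lists was 0.18 against -0.69 for white adipocytes. More fat tissue around the replicate 1 gland is a candidate explanation. Genes of the kidney, another neighbouring tissue, were lower in replicate 2 as well, with a median of -1.14 over the 4 with a mean count of at least 5, and this was seen after the data were examined. A second list of 18 adipocyte genes, not looked at before, had a median of -0.526 with 17 lower in replicate 2, among them Lpl at -0.84, Pck1 at -0.87 and Cd36 at -0.45, while Scd1, the most abundant at 112 ± 11.01 TPM, was at -0.28. All 18 had a mean count of at least 20 in this gland, so a change of their level within adipocytes or other cells stays open.

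Short RNA genes were lower in replicate 2, with all 50 snRNA and snoRNA genes under 250 nt below 0 and a median of -0.39. A difference in fragment length between the libraries would lower other short genes as well, and the 14 other genes under 250 nt had a median of -0.134, with 10 below 0. That value lies between the bounds set for a fragment length difference and for a lower level of small nuclear and nucleolar RNA alone. The 14 genes are few and of mixed classes, among them processed pseudogenes, scaRNA genes and mt-Atp8, which overlaps mt-Atp6. They therefore cannot tell these explanations apart. The length that the second quantifier subtracted did differ, at 213 nt in replicate 1 and 239 nt in replicate 2. Over all genes the median was -0.40 from 100 to 150 nt, -0.12 from 250 to 300 nt and -0.01 from 300 to 400 nt. The bins under 250 nt hold the snRNA and snoRNA genes, so this trend does not separate the explanations either.

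The same short genes were near 0 in the second quantifier. A fragment length longer than the transcript may account for it. The second quantifier subtracted 213 nt from a transcript's length in replicate 1 and 239 nt in replicate 2, and of genes shorter than this with at least 100 counts and a deposited posterior SD of the count of exactly 0, 100% fell under 0.1 of that count, 16 in replicate 1 and 11 in replicate 2, against 0 of 10132 and 0 of 9930 genes above 600 nt. Near-identical gene copies would leave such genes in place, so copies do not account for the losses among these genes. Without the limit on the posterior SD, genes longer than the subtracted length were lost too. These were 16.1% and 22.6% of genes from 300 to 400 nt in replicates 1 and 2. From 400 to 600 nt the share was 10.6% in both, and from 600 to 1000 nt 2.09%. The cause of the losses among these longer genes was not tested.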
